A study of Homo sapiens with 2 samples.

How the data were processed

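WaGa is an established human Merkel cell carcinoma line, a neuroendocrine skin cancer line that carries Merkel cell polyomavirus and grows in suspension. Domatinostat is a small-molecule inhibitor of class I histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. Per the labels' protocols, single-cell libraries were made with the 10x Genomics 3′ Chromium v2.0 chemistry, which counts unique molecular identifiers (UMIs) near the 3′ end of polyadenylated transcripts, and were sequenced on an Illumina instrument. There were 2 samples, 1 of cells without treatment and 1 of cells treated with the inhibitor, so each group had 1 library. The control was labelled as receiving no treatment, and the labels did not say whether it received the solvent. The labels gave neither the dose nor the time of treatment.

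The submitters' processing notes name Cell Ranger, Seurat and the genome build hg19, without versions. The annotation and the filters on cells were not given in the sources used here. The authors deposited 1 table for both samples, with 32742 genes and 10816 cells, whose values are on a natural log scale. Back-transformed, the deposited natural log values summed to 10000 in each cell, so that each value was the natural log of 1 plus the gene's counts per 10000 counts of the cell. Cells were assigned to the samples by the treatment word at the end of each cell name, and 0 columns were left without a sample. Nothing else in the table ties a cell to a sample, so the libraries are called labelled treated and labelled untreated throughout. In all, 48 cell barcodes occurred in both libraries and were kept as separate cells.

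In each cell, the smallest back-transformed value above 0 was taken as 1 UMI. With this step, 100% of the values above 0 were whole multiples within a tolerance of 1e-06, and in 100% of the cells the summed counts equalled the total that the step implied. UMI counts were recovered in this way for all cells, and the planned analysis of counts was applied to them. No filter on cells was added. The number of genes per cell reached 4995 in both libraries, and the mitochondrially encoded share reached 9.96% in the library labelled untreated and 9.99% in the library labelled treated. Doublets were not called; an alternative left out the 5% of cells with the most UMIs in each library.

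UMIs were summed per gene over the cells of each library and divided by the library total, in counts per 1000000 counts (CPM). The ratio of the library labelled treated to the library labelled untreated was given with a 95% exact interval (Clopper-Pearson on the gene's share of UMIs in the library labelled treated). Shares of cells above 0 have exact Clopper-Pearson intervals as well, and a share of 0 is given the limit of 3 cells of the total. With 1 library per group there was no replicate check and no test between conditions, and intervals and limits cover counting error only. A fold against a count of 0 was not given such an interval but was taken against 3 UMIs in the library, which is 0.0658 CPM in the library labelled untreated and 0.0499 CPM in the library labelled treated. Genes were counted as at least 2-fold higher or lower when they had at least 100 UMIs over both libraries.

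Before the data were examined, 23 gene lists, 8 sets of cell type markers and the alternatives were fixed. A list's median log2 ratio was taken over members with at least 50 UMIs and placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Members with a ratio of at least 1.5 either way were counted. The rule for named genes, also fixed beforehand, took the 14 highest and the 14 lowest ratios by the interval bound nearest to 1, up to 2 members at each end of every list, and 32 genes chosen by name. It left out mitochondrially encoded genes, ribosomal protein genes and clone-based names from the highest and lowest ratios. Any other gene named, the members of the cell type marker sets and the leading genes of clusters included, was picked after its values were seen. A few genes that the rule selects are not reported here.

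For comparisons per cell, each cell was thinned without replacement to 4351 UMIs, the 10th percentile of the shallower library, and shallower cells were left out. This removed 245 cells labelled untreated and 667 labelled treated. Free RNA in the droplets could not be gauged, since with 1 cell line no cell type lacking the genes was at hand. Cell cycle phases were called with scanpy from the S and G2/M lists, with both libraries scored together. Clusters were found within each library alone by the Leiden method at a resolution of 0.5, on 2000 variable genes, 20 principal components and 15 neighbours. Alternatives changed the scaling, the weighting of cells, the gene minimum, the pseudocount, the cells used and the thinning depth.

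The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19 and leidenalg 0.10.2, and the plots used matplotlib 3.10.9. The steps were tested on simulated data. In libraries of the observed sizes with 12812 genes, of which 200 were given known folds, the interval held the true ratio for 95.6% of unchanged genes and 95.0% of changed genes. In 100 simulations without change over those 12812 genes, counting error alone took at most 1 gene past 2-fold in either direction. The same simulation was run at the depth of the cells called G1 and of the cells of 7000 to 12000 UMIs. These simulations drew independent counts per gene, the model behind the interval, and left out the spread between cells. They therefore check the computation and gauge counting error only. No coordinates are given, because the annotation used here was of another genome build than the authors'. Genes with near-identical copies, among them the HLA genes, the histone genes, the metallothioneins, TRIM43, MBD3L2, LGALS7 and LGALS7B, have uncertain values because reads could be split or lost between copies.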

Results

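Single-cell transcriptomes of WaGa cells were compared without treatment and under the histone deacetylase inhibitor domatinostat, with 1 library each. The library labelled untreated held 4137 cells and 45562976 UMIs, with a median of 11125 UMIs and 3258 genes per cell. The library labelled treated held 6679 cells and 60160108 UMIs, with a median of 8578 UMIs and 2826 genes per cell. Mitochondrially encoded transcripts took 5.09% of UMIs in the library labelled untreated and 4.74% in the library labelled treated, and ribosomal protein transcripts took 20.5% and 21.4%. Directions below follow the treatment words in the cell names. Several genes that histone deacetylase inhibitors are known to induce, CDKN1A among them, were lower in the library labelled treated.

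The first comparison asked which genes differed in level between untreated and treated cells. Most of the large differences were genes lower in the library labelled treated. Of 12812 genes with at least 100 UMIs, 761 were at least 2-fold lower and 60 at least 2-fold higher, or 5.94% and 0.468% of the genes. The median log2 ratio over all 12812 genes was -0.00655. The lower genes were mostly weakly expressed, with a median of 4.15 CPM in the library labelled untreated and 1.35 CPM in the library labelled treated. Among 1545 genes at 100 CPM or more on average, 8 were at least 2-fold lower and 1, HIST1H4C, at least 2-fold higher. The 8 genes, named after their values were seen, were ID1, ID3, HSPB1, CSRP2, C1QL1, PPAP2C, LGALS7 and LGALS7B. ID1 and ID3 encode inhibitors of basic helix-loop-helix transcription factors, and HSPB1 a small heat shock protein. ID1 had 371.9 CPM in the library labelled untreated and 145.4 in the library labelled treated, and ID3 had 207.9 and 71.7 CPM. With no minimum beyond 1 UMI in each library the counts were 2885 lower and 622 higher, and with a pseudocount of 0.1 per 10000 they were 43 and 4. In cells of 7000 to 12000 UMIs they were 813 lower and 163 higher, where counting error alone gave at most 16 and 32 in 100 simulations. That window was not matched for the cell cycle between the libraries, as given below. In cells called G1 they were 1452 lower and 399 higher, where counting error alone gave at most 508 and 390.

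**Figure D1:**
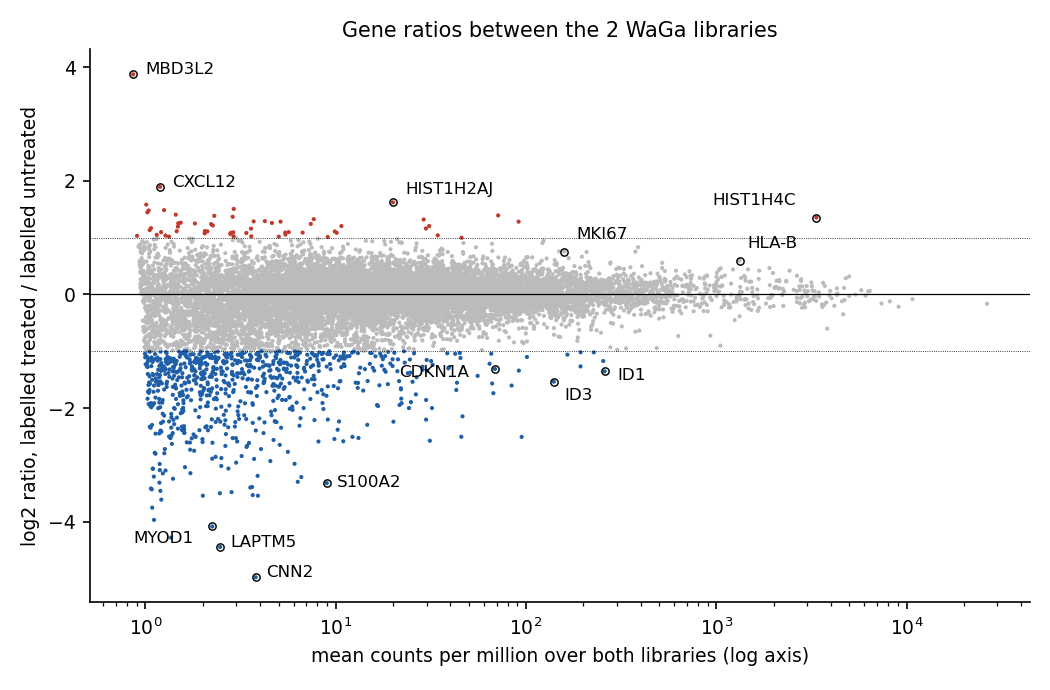
Log2 ratio of the library labelled treated to the library labelled untreated against mean CPM on a log axis, 1 point per gene with at least 100 UMIs and at least 1 UMI in the library labelled untreated. Genes at least 2-fold lower (blue, 761) outnumber those at least 2-fold higher (red), and most lie at low CPM.

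The lowest ratio belonged to CNN2, an actin-binding calponin, with 335 UMIs in the library labelled untreated and 14 in the library labelled treated, a ratio of 0.0317 (95% interval 0.0171 to 0.0539). LAPTM5, a lysosomal membrane protein of blood cells, had a ratio of 0.0458, and MYOD1, a transcription factor of skeletal muscle, a ratio of 0.0589 (0.0323 to 0.0995). The calcium-binding protein gene S100A2 had a ratio of 0.0999, from 16.3 to 1.63 CPM, and the transcription factor genes BATF3 and TGIF2 had ratios of 0.108 and 0.0947. PPP1R14A, TGFBR3L, SMARCA1, ZNF385C, PACSIN3, CEND1, CBR3 and NPTX1 completed the 14 lowest, with ratios from 0.0638 for SMARCA1 to 0.102 for TGFBR3L. In thinned cells, CNN2 had a UMI in 2.90% of cells labelled untreated and 0.116% of cells labelled treated, and unthinned in 7.40% and 0.210%.

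Replication-dependent histone genes, whose transcripts accumulate during DNA synthesis, made up 6 of the 14 highest ratios. HIST1H4C had 1887 CPM in the library labelled untreated and 4825 CPM in the library labelled treated, a ratio of 2.56 (2.54 to 2.58). HIST1H1B had a ratio of 2.63 (2.49 to 2.77), HIST2H2AC of 2.43, HIST1H2AI of 2.51 and HIST1H2AJ of 3.08, and HIST1H2AM had 16.6 and 41.4 CPM. In cells called G1 the direction turned, with a ratio of 0.912 (0.853 to 0.975) for HIST1H4C and a median log2 ratio of -0.13 over 39 HIST genes. Of the 60 genes at least 2-fold higher, 10 were HIST genes. The chemokine gene CXCL12 had a ratio of 3.72 from 23 and 113 UMIs, and SAMD15, CACFD1, GABARAP and MRPS24 had ratios of 2.84, 2.31, 2.24 and 2.31. TRIM43 and LEUTX, both targets of the embryonic transcription factor DUX4, had 0 UMIs in the library labelled untreated and 253 and 122 in the library labelled treated, at least 63.9-fold and 30.8-fold higher when the count of 0 is put at its limit of 3 UMIs. MBD3L2, another such target, had 5 and 97 UMIs. In each of these 3 genes most UMIs came from 2 cells, so the folds rest on those. All other cells of that library held 9 UMIs of TRIM43 and 5 of LEUTX, and without the 2 cells the log2 ratio of MBD3L2 was -0.14.

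The second comparison concerned antigen presentation and immune recognition. HLA-B and HLA-C, which encode class I heavy chains, were higher in the library labelled treated, and B2M, the light chain of every class I molecule, was lower. HLA-B had 1055 CPM in the library labelled untreated and 1592 in the library labelled treated, a ratio of 1.51 (1.49 to 1.53), and HLA-C a ratio of 1.38 (1.37 to 1.39). B2M had a ratio of 0.644 (0.631 to 0.657). In thinned cells, B2M had a UMI in 81.0% of cells labelled untreated and 66.3% of cells labelled treated, and unthinned in 94.0% and 81.3%. Of 16 measured members of the class I and peptide loading list, 1 was at least 1.5-fold higher and 4 at least 1.5-fold lower, and the median log2 ratio was -0.05, at percentile 35.1 of random lists. It was +0.06 among cells called G1. The immunoproteasome subunit gene PSMB8 had a ratio of 0.233 and the class I transactivator gene NLRC5 a ratio of 0.632, with a log2 ratio of 0.10 in cells called G1 from only 4 and 3 UMIs. The peptide transporter gene TAP1 had 8 and 2 UMIs. TAP2 and CD274, which encodes PD-L1, had 0 UMIs in all 4137 and 6679 cells, which by the limit of 3 cells allows a share of cells with a UMI of up to 0.0725% and 0.0449%.

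Interferon-response genes were mostly lower in the library labelled treated, with 0 of 17 measured members at least 1.5-fold higher and 8 at least 1.5-fold lower. Their median log2 ratio was -0.55 (percentile 1.39), with -0.17 under a pseudocount of 0.1 per 10000, -1.07 in cells called G1 and -0.36 in cells of 7000 to 12000 UMIs. OAS1 had a ratio of 0.237 and ISG20 of 0.262, while DDX58 had a ratio of 1.45 (1.01 to 2.10). The list of ligands of natural killer and T cells had 4 of 8 measured members at least 1.5-fold lower, with a median of -0.58 (percentile 0.95). MICB, a stress ligand of natural killer cells, had 138 and 33 UMIs and a ratio of 0.181 (0.120 to 0.266), and ULBP2, another, had a ratio of 0.262. The class II list had 3 measured members and a median of -2.18. These were HLA-DMA at 0.123, CD74 at 0.220 and IFI30 at 0.841. In cells called G1, CD74 had only 2 and 2 UMIs and a log2 ratio of 0.52.

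The third comparison concerned the cell cycle and growth arrest. Most proliferation genes had ratios above 1, but few reached 1.5-fold. Of 56 measured G2/M genes, 48 were above 1 and 8 below in the library labelled treated, 5 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.29 (percentile 100). MKI67 and TOP2A both had a ratio of 1.69, and CDK1 of 1.36, whereas the mitotic cyclin genes CCNB1 and CCNB2 had ratios of 0.728 and 0.769. Of 41 measured S phase genes, 30 were above 1 and 11 below, 4 were at least 1.5-fold higher and 0 lower, with a median of 0.18 (percentile 99.96), led by E2F8 at 1.83 and EXO1 at 1.64. The DNA repair list had a median of 0.14 (percentile 98.2). CDKN1A, which encodes the cell cycle inhibitor p21 and is a known target of histone deacetylase inhibitors, had 97.9 CPM in the library labelled untreated and 39.4 in the library labelled treated, a ratio of 0.403 (0.383 to 0.423). In thinned cells it had a UMI in 31.7% of cells labelled untreated and 13.99% of cells labelled treated, and unthinned in 56.1% and 24.9%. Of 23 measured genes of growth arrest, 2 were at least 1.5-fold higher and 6 at least 1.5-fold lower, with a median of -0.13 (percentile 3.02). CDKN1B and RBL2 were the highest at 1.64 and 1.54, and SESN2 had a ratio of 0.421. Among cells of 7000 to 12000 UMIs the G2/M median was 0.89 and CCNB1 and CCNB2 turned to the other direction. This window was not matched for the cell cycle. Clusters 3 and 5 of the library labelled untreated, led by mitotic genes, had medians of 14815 and 14275.5 UMIs, above the window. Cluster 3 of the library labelled treated, also led by mitotic genes, had a median of 10979.5, inside it. The window thus left out most cells of those untreated clusters, so these shifts cannot be told from the cut. The S phase median was 0.0337 in cells called G1, where the call itself asks for low scores of the S and G2/M lists and so limits the difference. The growth arrest median was -0.37 in cells called G1 and -0.26 with means on the log scale.

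**Figure D2:**
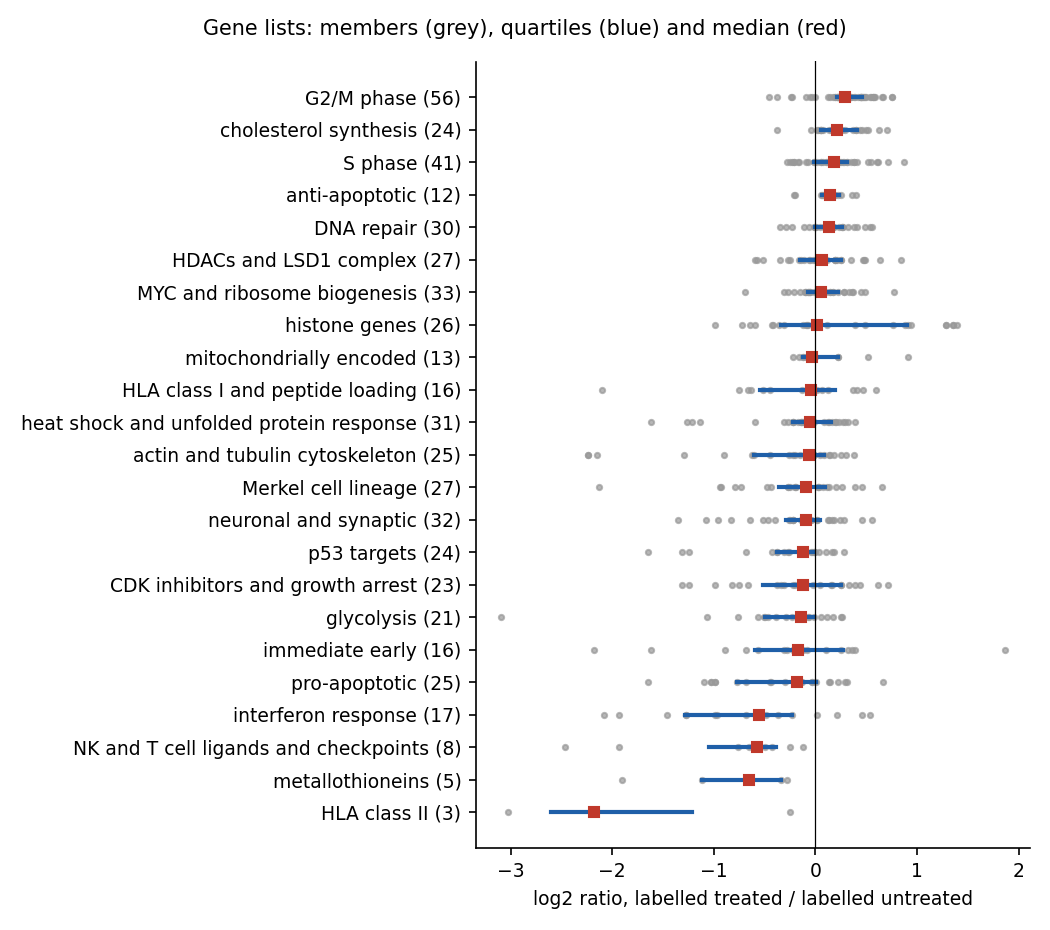
Log2 ratio of the library labelled treated to the library labelled untreated for 23 gene lists, with the number of measured members in parentheses (grey points, members; blue lines, quartiles; red squares, medians). G2/M genes have the highest median, 0.29, and the 3 measured class II genes the lowest, -2.18.

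Phase calls in thinned cells gave 12.1% (11.1% to 13.2%) of 3892 cells labelled untreated in G1, 58.6% in S and 29.3% (27.8% to 30.7%) in G2/M. Of 6012 cells labelled treated, 6.72% (6.10% to 7.38%) were called G1, 54.8% S and 38.5% (37.2% to 39.7%) G2/M. Unthinned, the G2/M shares were 30.1% and 39.9%. The G1 difference turned to the other direction when each library was scored alone, with 11.9% and 18.9% of cells. The size of the other differences depended on the setting: labelled treated minus labelled untreated, the S share differed by -3.78 percentage points, by -13.4 when thinned to the median depth and by -18.7 scored alone, and the G2/M share by 9.19, 17.8 and 11.8. The highest of the 2 scores lay within 0.05 of 0, where the G1 call ends, in 12.2% and 9.61% of cells. The calls rank cells by transcripts and do not measure division.

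**Figure D3:**
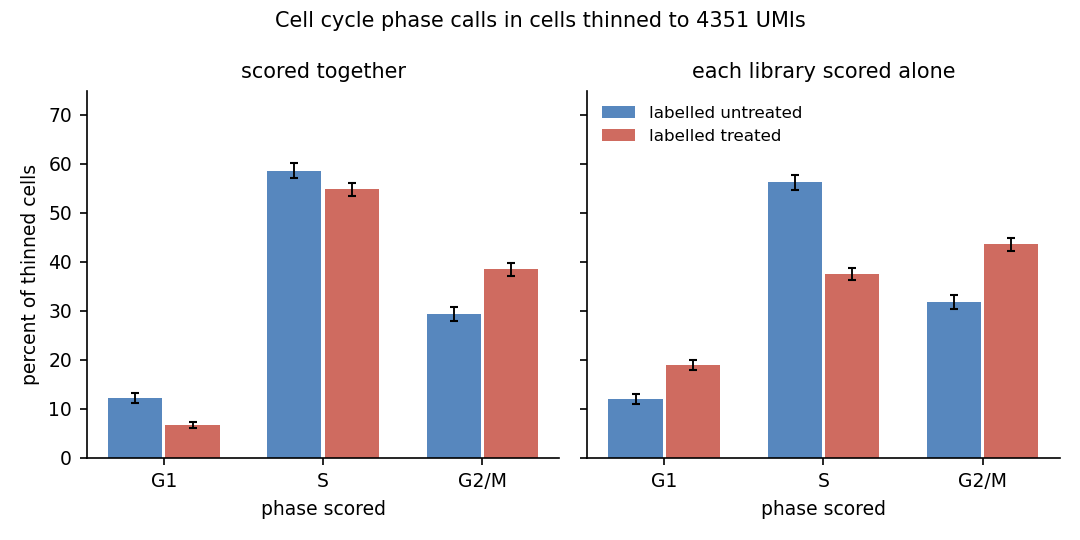
Percent of cells called G1, S and G2/M after thinning to 4351 UMIs, with both libraries scored together (left) and each scored alone (right). Bars start at 0 and error bars are 95% exact intervals, which cover counting error only. The G2/M share is larger in the library labelled treated in both panels, and G1 differs in direction between them. With both libraries scored together, 52.9% of cells labelled treated and called G2/M were rich in HIST1H4C, against 25.4% of those labelled untreated.

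The fourth comparison concerned cell death and stress. Of 25 measured pro-apoptotic genes, 1 was at least 1.5-fold higher and 8 at least 1.5-fold lower in the library labelled treated, with a median log2 ratio of -0.18 (percentile 2.32). BBC3, which encodes the BH3-only protein PUMA, had a ratio of 0.318 (0.277 to 0.364) and the death receptor gene TNFRSF10A of 0.467, while DIABLO had a ratio of 1.59. None of 12 measured anti-apoptotic genes reached 1.5-fold either way, and their median was 0.14. BCL2 had a ratio of 1.32, BCL2L1 of 1.15 and MCL1 of 1.07 (0.988 to 1.17). The p53 target list had a median of -0.12 (percentile 4.49), with 4 of 24 members at least 1.5-fold lower, CDKN1A, BBC3 and SESN2 among them. It is not independent of the lists above, with which it shares CDKN1A, GADD45A, SESN1, SESN2, BTG2, CCNG1, BBC3 and BAX. Metallothioneins, metal-binding proteins, were lower in 5 of 5 measured members, with a median of -0.66 (percentile 0.0200), from MT3 at 0.267 to MT1X at 0.826. Heat shock and unfolded protein genes had a median of -0.05 and 5 of 31 members at least 1.5-fold lower, with ATF3 at 0.325 and HSPB1 at 0.415. Immediate early genes had a median of -0.18, with IER3 at 0.221 and FOS at 3.64 from 10 and 48 UMIs.

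The fifth comparison concerned the drug's target class and the identity of the cells. HDAC1 and HDAC2 had ratios of 0.671 (0.640 to 0.703) and 0.842, and HDAC3 of 0.981 (0.928 to 1.04). KDM1A, which encodes the demethylase LSD1, had a ratio of 0.961. The list of deacetylases and the LSD1 complex had a median log2 ratio of 0.07 (percentile 80.1), with MTA2 highest at 1.80. The histone list had a median of 0.02 over members that went both ways, with 9 of 26 at least 1.5-fold higher and 4 at least 1.5-fold lower. H1F0, the linker histone gene of non-dividing cells, had a ratio of 0.782, and HIST1H2BJ of 0.502. Merkel cell lineage genes had a median of -0.09 (percentile 3.73), with 1 of 27 members at least 1.5-fold higher and 5 at least 1.5-fold lower. SOX2 had a ratio of 1.57, CHGA of 1.38, ATOH1 of 1.02 (0.871 to 1.19), the keratin gene KRT20 of 0.839 and KRT19 of 0.520. Neuronal and synaptic genes had a median of -0.09 (percentile 1.87), with SYN1 at 0.392 and DCX at 0.476.

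Of the metabolic and structural lists, cholesterol synthesis was the highest, with 22 of 24 measured members above a ratio of 1, 2 of them at least 1.5-fold, and a median log2 ratio of 0.21 (percentile 99.89). CYP51A1, a sterol demethylase gene of the pathway, had a ratio of 1.63 (1.41 to 1.90). Glycolysis genes had a median of -0.14 (percentile 2.04), with SLC16A3 at 0.117. Genes of MYC and ribosome biogenesis had a median of 0.06, the mitochondrially encoded genes of -0.03, and genes of the actin and tubulin cytoskeleton of -0.06 with 7 of 25 members at least 1.5-fold lower. ANXA2 and TUBB6 of the last list both had a ratio of 0.212.

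Most markers of other cell types were scarce in both libraries, with the exception of the keratinocyte genes KRT10 at 310.6 CPM and SFN at 88.3 CPM in the library labelled untreated. No T cell marker reached 50 UMIs. The markers given here come from the sets fixed beforehand and were picked after their values were seen. The measured markers of the other types that were 1.5-fold or more apart were all lower in the library labelled treated, the direction of most interferon-response and ligand genes. The B cell gene CD79A had a ratio of 0.289 from 4.26 to 1.23 CPM, the melanocyte gene PMEL of 0.113, the fibroblast genes COL1A1 and DCN of 0.315 and 0.661, the myeloid gene CD14 of 0.413 and the erythroid gene HBA1 of 0.337. The endothelial gene CLDN5 had a ratio of 1.01. Among keratinocyte genes, SFN had a ratio of 0.485 and KRT10 of 1.01.

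**Figure D4:**
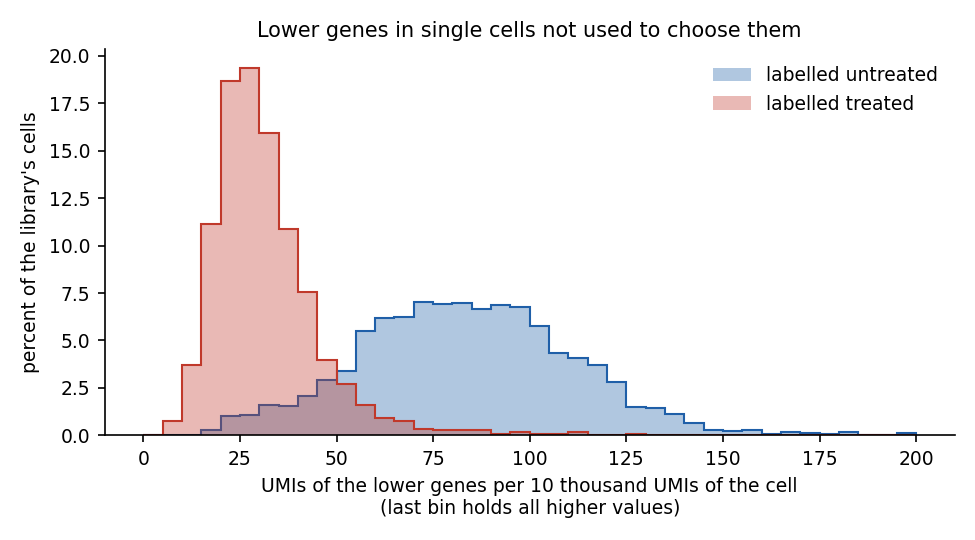
Percent of cells by their UMIs of 493 genes at least 2-fold lower, per 10000 UMIs of the cell, with the genes chosen on other cells of the same libraries. The median was 83.2 in 2065 cells labelled untreated and 28.9 in 3334 cells labelled treated.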

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

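The tests on cells called G1, on cells of 7000 to 12000 UMIs and without the 2 cells rich in DUX4 targets, and the simulations at the depth of the first 2, were chosen after the results were seen. With 1 library per group, no paired analysis was possible and no library could be left out. The filter at 500 genes and under 10% mitochondrially encoded counts removed no cell, so it says nothing. Scaling by the median ratio, a total without mitochondrially encoded and ribosomal protein genes, and equal weight for each cell gave 745, 743 and 782 genes at least 2-fold lower and 61, 62 and 63 higher, against 761 and 60; of the 761 genes, 745, 743 and 730 were again at least 2-fold lower. The cause of the shifts below was not tested unless stated.

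Genes at least 2-fold higher numbered 4 with a pseudocount of 0.1 per 10000, 399 in cells called G1, 163 in cells of 7000 to 12000 UMIs, 622 with no minimum beyond 1 UMI in each library and 22 with a minimum of 500 UMIs. Genes at least 2-fold lower numbered 43 with the pseudocount, 1452 in cells called G1, 813 in cells of 7000 to 12000 UMIs, 2885 with no minimum and 223 with a minimum of 500. The pseudocount shrinks the ratios of weakly expressed genes by construction, and a minimum changes the number of genes counted. Cells called G1 numbered 472 labelled untreated and 404 labelled treated; at their depth counting error alone gave a median of 356.5 higher and 458 lower genes in 100 simulations, up to 390 and 508, so that nearly all of the 399 higher genes there can come from it. In cells of 7000 to 12000 UMIs that error gave at most 32 higher and 16 lower. That window was not matched for the cell cycle, so part of its 163 higher genes may come from the cut.

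The median log2 ratio of class I and peptide loading was -0.0203 with equal weight for each cell, -0.0189 with the pseudocount and 0.0595 in cells called G1. That of interferon response was -0.17 with the pseudocount, -1.07 in cells called G1 and -0.36 in cells of 7000 to 12000 UMIs. S phase gave 0.13 with the pseudocount, 0.11 with means on the log scale, 0.13 without the 5% of cells with the most UMIs, 0.0337 in cells called G1 and 0.14 in cells of 7000 to 12000 UMIs. The G1 call asks for low scores of the S and G2/M lists, which limits the difference. G2/M gave 0.34 with equal weight for each cell, 0.39 on the log scale, 0.35 without the cells with the most UMIs and 0.89 in cells of 7000 to 12000 UMIs. The last value cannot be told from the cut, as that window was not matched for the cell cycle. Growth arrest gave -0.26 on the log scale and -0.37 in cells called G1, and pro-apoptotic genes -0.13 with the pseudocount and -0.13 with 500 UMIs per member. MYC and ribosome biogenesis turned to -0.00766 on the log scale and -0.0176 in cells of 7000 to 12000 UMIs, heat shock to 0.0139 in those cells and the mitochondrially encoded genes to 0.0172 in cells called G1. These 3 lists and the 14 not named in this paragraph had 170 values. Of them, 133 stayed within the full libraries' counting interval, 33 left it and the 4 just given changed sign.

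The share of cells called G1, labelled treated minus labelled untreated, turned from -5.41 to 6.94 percentage points with each library scored alone. The S share differed by -13.4 points when thinned to the median depth and -18.7 scored alone, and the G2/M share by 17.8 and 11.8 points. Shares of cells with a UMI turned to -1.24 points for BCL2L1 and -1.45 for MCL1 without thinning, and of 41 such shares 26 others moved and 13 stayed.

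Of 1239 values of named genes under alternatives, 970 stayed within the full libraries' interval, 250, from 112 of 125 genes, left it and 19 changed sign. The larger error of a subset of cells was not used, so shifts there may lie within it. MBD3L2 had a log2 ratio of -0.38 without the 5% of cells with the most UMIs, -0.93 in cells of 7000 to 12000 UMIs and -0.14 without the 2 cells, which hold most of its UMIs. In cells called G1 the log2 ratio was -0.13 for HIST1H4C, -0.31 for HIST1H1B, 0.10 for NLRC5 (4 and 3 UMIs), 0.11 for KDM1A, 0.0256 for KRT20, 0.52 for CD74 (2 and 2 UMIs), -0.0140 for BIRC6, -0.50 for MDM2, -0.34 for HSPA1B, -0.0508 for KLF6, -0.0910 for PDK1, -0.0234 for BRCA1 and 0.0391 for FANCL. In cells of 7000 to 12000 UMIs it was 0.36 for CCNB1, 0.33 for CCNB2 and 0.20 for CHEK2. That window was not matched for the cell cycle, and the G1 call leaves out cells rich in histone transcripts. The turns of CCNB1, CCNB2, HIST1H4C and HIST1H1B thus cannot be told from the choice of cells.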

Other observations

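The tests and simulations in cells called G1 and in cells of 7000 to 12000 UMIs, the test on a minority of cells, the rule that set aside the S phase test, the scaling check on the histone test and the loosened bound for the 2 cells were chosen after the results were seen. The idea of exchanged names also came from these data, after CDKN1A and other genes had been seen lower in the library labelled treated.

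Clustered alone, the library labelled untreated gave 8 clusters and the library labelled treated 6, and cell cycle genes led many of them. In the library labelled untreated, cluster 3 was led by CCNB1, CCNB2 and DEPDC1 and cluster 5 by PIF1, UBE2C and PLK1, with 94.8% and 99.0% of cells called G2/M. Cluster 4 was led by HIST1H4C and HIST1H1B. Cluster 1, whose cells had a median of 7588 UMIs, was led by ID1 and included H1F0, GADD45G and ID3 among its leading genes. In the library labelled treated, cluster 0 was led by HIST1H4C and cluster 3 by CCNB1 and CDC20, and cluster 1 by CAMK2B, SLC7A4, SOX3 and DLL3. Cluster 5 of that library had the lowest median, 4546 UMIs, and was led by CTNNB1 and SPC24. Shares of clusters were not compared between libraries.

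Of the 761 genes at least 2-fold lower in the library labelled treated, most were weakly expressed but 8 had 100 CPM or more on average. Histone deacetylase inhibitors are known to raise silent and weakly expressed genes, which is the other direction. How many genes such an inhibitor lowers in these cells is not known here, and the labels gave neither dose nor time. A list of 16 genes that textbooks give as induced by such inhibitors was written from genes whose own values had not been seen, although 10 of them sit in lists whose medians had; 13 had at least 50 UMIs, 11 of these had a ratio below 1, and the median log2 ratio was -0.4009, at percentile 0.035 of matched random lists, as an exchange of the names would give. The lower genes kept a median log2 ratio of -1.481 in cells called G1, which argues against cell cycle composition only as far as the phase calls can be trusted. The G1 difference between libraries changed direction when each was scored alone. UMIs per cell are argued against by a median of -1.47 in cells of 7000 to 12000 UMIs, a window not matched for the cell cycle. A minority of different cells is argued against, since with genes chosen on other cells 97.87% of cells labelled untreated lay above the median cell labelled treated. A candidate explanation is that the treatment words in the cell names are exchanged, in which case each direction in the text would be turned around. A response of these cells in which such genes fall stays open. A difference in culture, preparation or free RNA between the libraries stays open too, since 1 library per group cannot tell it apart from treatment. HLA-B and HLA-C, higher in the library labelled treated, may speak for the names as they stand if the inhibitor raises class I genes here. Both libraries come from 1 cell line, so no sequence marker was at hand to settle it.

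Of 39 HIST genes with at least 100 UMIs, 31 had a ratio above 1 in the library labelled treated, 10 of them at least 2-fold. Others such as HIST1H2BJ at 0.502 were lower. The median log2 ratio was -0.133 in cells called G1, but 0% of those in either library had at least 50 HIST1H4C UMIs per 10000. Over all cells, 32.4% of cells labelled treated had at least 50 HIST1H4C UMIs per 10000, against 11.8% of cells labelled untreated. Among those cells the median level was 118 and 98.1, a ratio of 1.2, whereas multiplying every cell labelled untreated by the overall ratio of 2.56 would give a ratio of 2.26 and 15.3% of cells. More cells in a histone-expressing state is thus a candidate explanation. Within cells called S the median log2 ratio of HIST genes was 0.892, which the bound written beforehand would have read as evidence against more cells in S phase. That bound was set aside, because at most 23.7% of cells called S reached 50 HIST1H4C UMIs per 10000. Of cells called G2/M, 52.9% labelled treated and 25.4% labelled untreated reached that level. The S call thus did not pick out the cells rich in histone transcripts. Replication was not measured otherwise, so more cells in S phase cannot be told apart. The share of cells called S, labelled treated minus labelled untreated, differed by -3.78 percentage points. A difference in polyadenylated histone transcripts, and the treatment itself, were not tested.

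In the library labelled treated, 2 cells held 244 of 253 UMIs of TRIM43, 117 of 122 of LEUTX and 91 of 97 of MBD3L2, all known DUX4 targets. The wider set was seen in 1 of them, with 66 UMIs of TRIM43, 111 of LEUTX, 89 of MBD3L2, 9 of ZSCAN4, 17 of PRAMEF1, 3 of PRAMEF12 and 11 of KHDC1L. The other had mainly TRIM43, with 178, 6, 2, 0, 0, 7 and 0. DUX4 itself had 0 UMIs in both libraries. Nothing here shows that its transcripts could be detected, so that count does not tell whether DUX4 was expressed. Their share of Merkel cell lineage UMIs lay at percentiles 9.942 and 98.98 of their library, where a percentile under 1 was set for cells of another origin. The bound written beforehand asked for both cells below the 95th percentile, which 1 exceeded, so by that bound the test was undecided. An excess of lineage transcripts is nothing that a foreign cell predicts, so that bound was dropped after the values were seen. Read so, the shares argue only weakly against cells of another origin. HES6 alone gave 3882 of the 8211 CPM of the list's measured members in that library. The 2 cells had 39 and 47 UMIs of CHGA, but 1 and 0 of KRT20. Both cells were deep, at percentiles 95.3 and 95.7 of UMIs, so a doublet of a WaGa cell with another cell may still account for them. A rare state of WaGa cells stays open as a hypothesis, and with 2 cells in 1 library its relation to treatment was not tested.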
